A study of Mus musculus with 12 samples.

How the data were processed

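Gene expression was measured in 12 mouse kidneys with one-colour Agilent microarrays, on which Cy3-labelled RNA binds to printed probes and the brightness of each spot is read by a scanner. The labels give 4 groups of 3 male mice on a C57 background. These are wild-type (WT) mice after a sham operation, WT mice 24 h after ischemia-reperfusion injury (IRI), Jaml knockout (KO) mice after a sham operation, and KO mice 24 h after IRI. In IRI the blood supply of both kidneys is closed for a time and then restored. The series text gives 40 min of clamping and the protocol text gives 30 min of ligation, and nothing in the labels settles which was used. Per the labels the 3 samples of a group are independent, so each array is taken as 1 animal.

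Each deposited scanner file holds spot intensities from Agilent Feature Extraction 10.7.1.1, per the file headers. The processed signal in these files is an intensity on a linear scale that the scanner software had background-corrected and detrended within the array, with no scaling between arrays, per the file headers. The files also hold the mean foreground intensity, the median local background intensity and flags per spot, as deposited. A second deposited table holds the authors' log2 values, and limma is named in the submitters' processing notes without a version. Within each array these log2 values followed the log2 processed signal with r of at least 0.9995, and every array had a median of 5.71, which is the pattern of quantile normalization. They differed from quantile-normalized log2 processed signals by a median of 0.0429 and at most 1.31. Neither centring per gene nor another sign was found in them.

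Each array has 62976 spots, of which 59305 are not controls, for 56605 different probes. Control spots and spots flagged as outliers were left out, spots of the same probe were averaged, and the processed signal was taken to log2 and reduced by the 75th percentile of its array. All levels below are on this scale. A probe was kept if it was well above background on at least 3 of the 12 arrays, which left 39449 probes. Each gene was represented by its kept probe with the highest mean over all 12 arrays, which gave 25947 genes and transcripts, of which 16490 had an ordinary gene symbol. Symbols were updated through the RefSeq gene table for GRCm38.p6 by accession. That gave a symbol to 32994 probes, and 23611 kept the name in the files. Probe coordinates are those of the files, on mouse build mm9 (NCBI37).

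Comparisons were fitted with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 12 arrays, so that the groups share an estimate of the spread with 8 residual degrees of freedom. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. Errors of log2 fold changes are standard errors from this fit, with n = 3 per group, and assume the same spread in every group. The comparisons were IRI against sham in each genotype, KO against WT in sham and in IRI, and the interaction, which is the IRI response of KO minus that of WT. For 35 gene lists fixed before the data were examined, limma's camera tested whether a list moved relative to all other genes, with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. The score of a list on an array is the mean of its members after each was centred on its mean over 12 arrays.

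The genes named were chosen by a rule fixed before the data were examined. Jaml, Havcr1, Lcn2 and Clec4e are always given. For each comparison the rule adds the 6 largest rises and 6 largest falls among genes past the threshold with an ordinary symbol whose groups did not overlap and which were well above background on all 3 arrays of the higher group. For each list past the threshold it adds up to 4 members that moved with the list and up to 2 that moved against it. Some genes that the rule takes are not reported here. Where a probe was not well above background on any array of the lower group, the change is given as a bound. The bound sets the mean of the higher group against the mean, per array, of the higher of the probe's own signal and the lowest signal among probes well above background. It holds for the kept probe in the fit as planned, and other probes of a gene or alternative fits can give smaller changes.

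Signal was well above background for 35598 to 38522 probes per array (62.9% to 68.1%), no probe was saturated, and the median processed signal lay between 46.6 and 63.8. The precision of each comparison is limited by 3 arrays per group. On simulated arrays with the spread of the real ones and 25928 genes, the fit recovered 35.0% of 100 genes changed 2-fold and 80.0% of 100 genes changed 4-fold for WT IRI against WT sham. For KO IRI against WT IRI it recovered 52.0% and 86.0%. Both simulations used the same spread per gene, pooled over the groups, so the gap between them comes from the random draw. They do not show that either comparison is more precise, and they leave out unequal spread between groups. They also changed fewer genes than passed in the data, and the adjusted threshold depends on that number. The shares recovered are therefore not those of the real comparisons.

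The files place all 6 WT arrays on 1 slide, read in 1 scan, and all 6 KO arrays on a second slide, read in another scan. Slide, scan and genotype therefore cannot be told apart, and no fit of KO against WT can have the slide as a term. IRI and sham arrays of a genotype share a slide, so those comparisons lie within slides. A shift of a gene by the same factor on all arrays of a slide cancels in the interaction.

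Alternatives fixed before the data were examined were quantile normalization, normexp background correction with an offset of 50, the authors' log2 values, no filter or a stricter filter on dim probes, the mean over the probes of a gene, only the arrays of the comparison, the replicate number as a block, the slide as a block, the trend and robust options of eBayes, array weights, and leaving out each array in turn. The scan was not run as a block of its own because it divides the arrays exactly as the slide does.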

Results

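The data are expression profiles of 12 kidneys, 3 each from WT sham, WT IRI, KO sham and KO IRI mice. Jaml encodes a junctional adhesion molecule-like protein found on leukocytes, and the design asks whether its loss changes the kidney's response to ischemia and reperfusion. Correlations between arrays of a group over all genes lay between 0.968 and 0.995. The lowest were those of WT IRI replicate 1 with replicates 2 (0.968) and 3 (0.976), and its root mean square deviation from its group mean was 0.579 log2 units, against 0.205 to 0.433 on the other 11 arrays. In a principal component analysis the first component, with 34.2% of the variance, placed all 6 IRI arrays above all 6 sham arrays. The second, with 24.3%, placed the WT sham arrays at 58.3 to 64.6, the WT IRI arrays at 40.4, -5.4 and -1.6, the KO sham arrays at -35.7 to -6.1 and the KO IRI arrays at -61.8 to -42.1.

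The targeted gene was measured by 1 kept probe, on chromosome 9 at 44915486 to 44915545 (mm9). Jaml was lower in KO than in WT kidneys after sham operation, with a log2 fold change of -2.79 ± 0.56 (SE, n = 3 per group, limma adjusted p = 0.0152). The WT sham arrays read -0.25, -0.26 and -0.43 and the KO sham arrays -3.54, -2.59 and -3.18. After IRI the difference was -1.57 ± 0.56 and did not pass the test (adjusted p = 0.153), with WT arrays at 0.55, -1.80 and -1.64 and KO arrays at -1.89, -2.70 and -3.0. Jaml did not pass after IRI within either genotype, at -0.64 ± 0.56 in WT (adjusted p = 0.480) and 0.58 ± 0.56 in KO (adjusted p = 0.612), nor in the interaction (1.22 ± 0.79, adjusted p = 0.612). Leaving out WT IRI replicate 1 moved the difference between genotypes after IRI to -0.81, and the sham difference missed the threshold without WT sham replicate 1, KO sham replicate 1 or KO sham replicate 3 (-2.76, -2.57 and -2.75). The probe stayed well above background on all 6 KO arrays. Whether it lies in the deleted part of the gene is not given in the sources used here, so residual signal neither checks nor contradicts the labels.

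**Figure D1:**
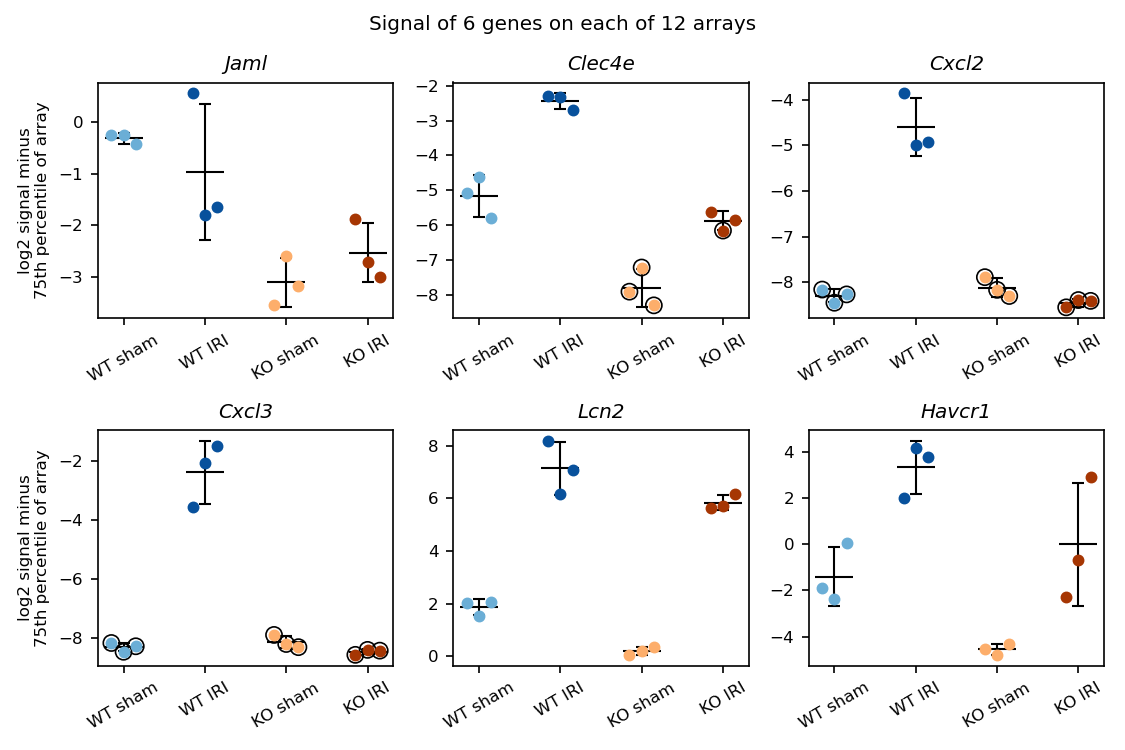
Log2 processed signal minus the array's 75th percentile (y axis) for Jaml, Clec4e, Cxcl2, Cxcl3, Lcn2 and Havcr1 in the 4 groups (x axis). Points are arrays, bars are means with SD (n = 3), and circled points were not well above background. Cxcl2 and Cxcl3 were well above background on the 3 WT IRI arrays and on none of the other 9, and Lcn2 was higher on every IRI array than on any sham array.

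The response of WT kidneys to IRI included large rises in markers of damaged tubule epithelium. Sprr2f, a small proline-rich protein of stressed epithelia, rose by 9.11 ± 1.16 on the log2 scale, though only 1 of 3 WT sham arrays measured it well above background. Its rise ran from 6.25 to 9.91 over the alternative fits. Krt20, a keratin of injured tubules, rose by 6.62 ± 0.77, Lcn2, which encodes the injury marker NGAL, by 5.27 ± 0.41, and Havcr1, which encodes KIM-1, by 4.73 ± 1.15 (adjusted p = 0.0273). The acute-phase gene Saa2 rose by 6.62 ± 0.99. Vgf, Sult1e1 and Grp were not well above background on any WT sham array and were at least 60.4-fold, 85.8-fold and 23.2-fold higher after IRI. Another probe of Vgf rose by only 2.33 on the log2 scale. Over the alternative fits the lowest log2 rises of Vgf, Sult1e1 and Grp were 3.80, 4.12 and 2.45. Of the 18 tubule injury genes on the fixed list, 12 rose and 0 fell, or 16 and 0 adjusted over the list alone (camera adjusted p = 4.22e-11). With an estimated correlation none of the 35 lists passed in this comparison, and this one had an adjusted p = 0.195 with an estimated correlation. Markers of healthy nephron segments went the other way. Of 23 proximal tubule genes 6 fell and 0 rose, or 10 fell adjusted over the list alone, including Slc5a12 (-1.74 ± 0.41), the phosphate transporter Slc34a1 (-1.03 ± 0.21) and the endocytic receptor Lrp2 (-0.81 ± 0.16). The list passed camera at adjusted p = 7.02e-05 (adjusted p = 0.195 with an estimated correlation). In the thick limb and distal tubule 4 of 13 genes fell, among them Pvalb (-2.02 ± 0.45) and Egf (-1.09 ± 0.26), with camera adjusted p = 0.0202. In the collecting duct 2 of 12 fell, Slc26a4 and Atp6v0d2, with camera adjusted p = 0.0146. Their adjusted p values with an estimated correlation were 0.195 and 0.294.

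Neutrophil genes rose while markers of most other leukocytes fell. Of 14 neutrophil genes 8 rose, including the chemokine receptor Cxcr2 (3.96 ± 0.96, measured on 1 of 3 sham arrays), Retnlg (3.83 ± 0.59) and S100a8 (3.59 ± 0.66), and Ly6g fell (-0.95 ± 0.19). The rise of Cxcr2 ran from 1.375 to 5.232 over the alternative fits. The camera adjusted p of the neutrophil list was 7.02e-05, and the adjusted p = 0.195 with an estimated correlation. Of 22 cytokine and chemokine genes 9 rose, among them Il6 (5.54 ± 1.29, measured on 2 of 3 sham arrays), Il11 (4.04 ± 1.03) and Cxcl2 (at least 2.67-fold), while Cxcl10 (-2.65 ± 0.66) and Ccl5 (-2.20 ± 0.57) fell. Clec4e, which encodes the macrophage receptor Mincle, rose by 2.72 ± 0.33. T and NK cell genes fell furthest. Of the 15 measured 12 fell, including Cd3g, Cd8b1 and Nkg7 (-4.27 ± 0.76, -3.99 ± 0.87 and -3.97 ± 0.74), and the list had a median log2 fold change of -3.26 (camera adjusted p = 4.67e-09, and adjusted p = 0.195 with an estimated correlation). Dendritic cell and antigen presentation genes fell in 6 of 11, led by the class II transactivator Ciita (-3.69 ± 0.71), and interferon response genes in 4 of 17, or 12 of 17 adjusted over the list alone. Their camera adjusted p values were 1.22e-05 and 8.08e-06, and the adjusted p = 0.195 and 0.294 with an estimated correlation. The guanylate-binding proteins Gbp11 and Gbp8, made in response to interferon, fell by 4.98 ± 0.77 and 4.73 ± 0.73. Among macrophage and monocyte genes 6 of 17 fell, including Aif1 (-1.78 ± 0.30), and 2 rose, Cd14 (2.91 ± 0.80) and Cd68 (1.46 ± 0.34). Cell cycle genes fell in 6 of 18, including Mki67 (-2.52 ± 0.64) and Top2a (-2.49 ± 0.54). The camera adjusted p was 0.00712 for macrophages and 0.000154 for the cell cycle, with adjusted p = 0.294 and 0.379 with an estimated correlation. These falls are set against WT sham kidneys that differed among themselves. Replicates 1 and 2 had T and NK cell scores of 2.88 and 2.94 and replicate 3 had 0.50, while replicate 3 had the highest interferon score, 2.86 against 1.20 and 1.26.

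Markers of blood and fat moved in the same comparison. The hemoglobin genes Hbb-b1 and Hba-a2 rose by 2.74 ± 0.43 and 2.68 ± 0.40, with 6 of 8 erythrocyte genes higher, and as members of a family with close copies they are uncertain as single genes. Cidec, a lipid droplet protein, rose by 5.64 ± 0.51. Plin1 was at least 18.15-fold higher by its kept probe, while its other probes rose by 2.91 and 2.12 on the log2 scale. Of 9 adipose genes 3 were past the threshold. The camera adjusted p values were 0.000709 and 0.000438, and the adjusted p = 0.195 and 0.294 with an estimated correlation. In all, 3109 of 25947 genes passed, 1577 higher and 1532 lower, of which 1684 changed at least 2-fold, and the groups did not overlap for 32.3% of genes where chance gives 10%. A fit to the 6 WT arrays alone, which lie on 1 slide, gave 417. With the slide as a block the count had to be 3109 again, because the slide term adds nothing to the group terms. The count was 861 without WT sham replicate 1, 846 without WT sham replicate 2, 1205 without WT IRI replicate 3 and 4675 without WT IRI replicate 2, and it was 8922 with array weights.

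KO kidneys also responded to IRI with tubule injury genes and with the acute-phase genes Saa2 and Saa3. Saa2 rose by 8.22 ± 0.99, the peptide precursor Tac4 by 6.61 ± 0.49 (measured on 1 of 3 KO sham arrays), Krt20 by 5.67 ± 0.77 and Lcn2 by 5.64 ± 0.41. The rise of Tac4 ran from 3.72 to 6.97 over the alternative fits. Saa3 and the protease Mmp7 were not well above background on any KO sham array and were at least 32.3-fold and 12.99-fold higher. Their lowest log2 rises over the alternative fits were 2.84 and 1.74. Havcr1 rose by 4.54 ± 1.15 (adjusted p = 0.0458), a call lost in 12 of 23 alternative fits, including those without WT sham replicate 1 or 2, WT IRI replicate 2 or 3, KO IRI replicate 2 or 3, or any 1 of the KO sham replicates. The tubule injury list had 5 of 18 genes higher, or 14 adjusted over the list alone (camera adjusted p = 1.50e-12, and adjusted p = 0.151 with an estimated correlation). Proximal tubule genes fell in 9 of 23, or 16 adjusted over the list alone, led by Slc7a13 (-2.10 ± 0.19), the amino acid transporter Slc6a19 (-1.48 ± 0.22) and Slc34a1 (-1.41 ± 0.21). That list had a camera adjusted p of 2.60e-10, and an adjusted p = 0.110 with an estimated correlation. Pvalb (-2.64 ± 0.45) and Egf (-1.21 ± 0.26) fell among 3 of 13 thick limb and distal tubule genes. Oxidative phosphorylation genes had a median of -0.35, with Ndufs1 (-0.60 ± 0.13, a call lost in 12 of 23 alternative fits) past the threshold over all genes and 14 of 15 lower adjusted over the list alone (camera adjusted p = 3.03e-05, and adjusted p = 0.396 with an estimated correlation).

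Neutrophil genes rose in 4 of 14, including S100a8 (4.09 ± 0.66) and S100a9 (3.84 ± 0.67), with camera adjusted p = 0.000167 (adjusted p = 0.239 with an estimated correlation). The lectin receptor gene Clec4d rose by 5.12 ± 0.72, measured on 1 of 3 KO sham arrays, with values from 1.92 to 5.90 over the alternative fits. Clec4e passed the test (adjusted p = 0.0109), but it was well above background on none of the KO sham arrays and on only 2 of 3 KO IRI arrays, so no fold is given, and with normexp its log2 fold change was 0.05. B and plasma cell genes fell in 3 of 8, with Ms4a1 at least 3.13-fold lower (camera adjusted p = 0.000686, and adjusted p = 0.141 with an estimated correlation). Of 15 T and NK cell genes none passed, with a median of -0.98. Complement and coagulation genes rose in 3 of 15, Fgg (4.28 ± 0.89), C3 (3.20 ± 0.49) and C5ar1 (1.84 ± 0.39), and 4 of 15 heat shock and unfolded protein response genes rose, led by Trib3 (1.94 ± 0.37). Their camera adjusted p values were 0.00115 and 0.00154, and the adjusted p = 0.439 and 0.266 with an estimated correlation. Among the largest falls, the sperm protein gene Smcp fell by 4.87 ± 0.72 and the interferon-induced chemokine Cxcl9 by 3.45 ± 0.78, and Apol7c was at least 6.30-fold lower. In all, 1598 genes passed, 546 higher and 1052 lower, and the groups did not overlap for 35.7% of genes where chance gives 10%. With quantile normalization the split was 805 higher and 819 lower. A fit to the 6 KO arrays alone gave 2442. The count was 454, 740 and 510 without KO sham replicates 1, 2 and 3, 923, 1024 and 733 without KO IRI replicates 1, 2 and 3, and 3250 without WT IRI replicate 1, and it was 5756 with array weights.

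The IRI responses of the genotypes were set against each other gene by gene. Across all genes the log2 fold changes had a Pearson correlation of 0.60 and a slope of KO on WT of 0.47. Genes are not independent replicates, so no p is given. Among the 3109 genes past the threshold in WT, 90.8% had the same sign in KO, with a slope of 0.52. Error in the WT values lowers both slopes, and the second covers only genes picked by their WT test. Neither slope therefore measures how much smaller the KO response was. The SD of the log2 fold changes over all genes was 0.743 in WT and 0.588 in KO. Both genotypes raised 348 genes, where independent lists of these sizes would share 33.2, and both lowered 476, where 62.1 would be shared. In 8 genes the calls had opposite signs. Each genotype has its own sham arrays, so the fold changes of the comparisons share no arrays. The calls do share an estimate of the spread, which is pooled over all arrays. Without WT IRI replicate 1, the count for KO IRI against KO sham went from 1598 to 3250. Genes with a small pooled spread pass more easily in both comparisons. The number of calls shared without a common response can therefore exceed 33.2 and 62.1.

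**Figure D2:**
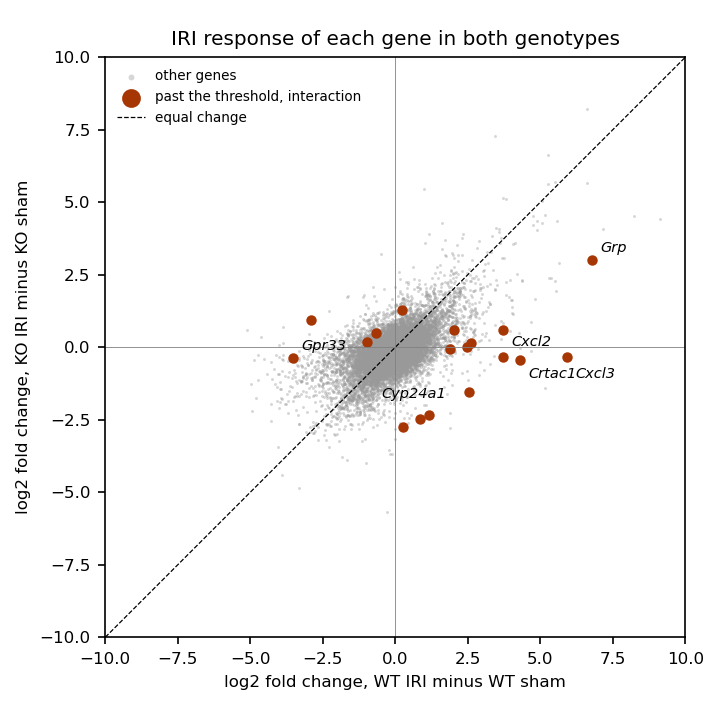
Log2 fold change after IRI in WT (x axis) and KO (y axis) for each of 25947 genes, with the 18 genes past the threshold of the interaction in brown. The dashed line marks equal change, and across all genes the slope of KO on WT was 0.47, a value that error in the WT fold changes lowers.

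Sham-operated KO kidneys were far lower than sham-operated WT kidneys in interferon-induced, antigen presentation and T and NK cell genes. Ubd, an interferon-induced ubiquitin-like protein, was lower by a log2 fold change of -7.65 ± 1.36, and the guanylate-binding proteins Gbp6, Gbp9 and Gbp11 by -6.61 ± 1.06, -5.83 ± 1.06 and -5.79 ± 0.77. Of 17 interferon response genes 13 were lower and 0 higher, including Gbp2 (-5.12 ± 1.24) and Irf7 (-3.52 ± 0.46). This list had camera adjusted p = 5.79e-20 and adjusted p = 0.103 with an estimated correlation. Dendritic cell and antigen presentation genes were lower in 9 of 11, including Ciita (-4.01 ± 0.71), H2-Aa (-3.77 ± 0.80) and Cd74 (-3.59 ± 0.72). T and NK cell genes were lower in 8 of 15, or 13 adjusted over the list alone, led by the granzyme genes Gzmb (-5.07 ± 0.88) and Gzma (-3.60 ± 0.78). Cell cycle genes were lower in 9 of 18, including Top2a (-3.04 ± 0.54) and Mki67 (-2.68 ± 0.64). The camera adjusted p values of these lists were 5.45e-11, 8.56e-11 and 4.15e-14, and the adjusted p = 0.0985, 0.164 and 0.128 with an estimated correlation. None of 8 B and plasma cell genes passed, with a median of 0.26. The lower T and NK cell and cell cycle genes rest on WT sham replicates that differed, since replicates 1 and 2 had cell cycle scores of 1.69 and 1.66 and replicate 3 had 0.42.

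Innate immune genes were lower in KO sham kidneys as well. Complement genes C4b (-5.54 ± 0.83), C3 (-4.41 ± 0.49) and C1ra (-2.42 ± 0.45) were among the 5 of 15 complement and coagulation genes that were lower. C4b has a near copy, C4a, whose probe moved likewise (-5.68 ± 0.85). Cxcl10 (-4.64 ± 0.66) and Ccl2 (-2.93 ± 0.53) were among the 6 of 22 cytokine genes that were lower. Tnf was higher (0.65 ± 0.14), but its value over all its probes was -1.02. Macrophage and monocyte genes were lower in 6 of 17, including Fcgr1 (-2.32 ± 0.39) and C1qa (-1.78 ± 0.25), and neutrophil genes in 5 of 14, including S100a8 (-3.08 ± 0.66). Mincle and C-type lectin signalling genes were lower in 5 of 11. Clec4e was not well above background on any KO sham array and was at least 1.61-fold lower, and the adaptor Fcer1g was lower by 1.49 ± 0.17. Regulated cell death genes were lower in 8 of 23, led by the necroptosis effector Mlkl (-2.24 ± 0.47). The lectin and cell death lists passed camera with an estimated correlation too (adjusted p = 0.0210 for both), and the complement, cytokine, macrophage and neutrophil lists did not (adjusted p = 0.128, 0.117, 0.0985 and 0.164 with an estimated correlation). In the tubule injury list Lcn2 (-1.67 ± 0.41), Vcam1 (-1.97 ± 0.33) and Atf3 (-2.01 ± 0.44) were lower, while Havcr1 at -3.14 ± 1.15 did not pass (adjusted p = 0.122). Higher in KO sham were Crabp1 (3.32 ± 0.40), Thbs4 (3.27 ± 0.66, measured on 2 of 3 WT sham arrays), Cox6a2 (3.10 ± 0.73) and the proximal tubule transporters Slc6a19 (1.12 ± 0.22) and Slc5a2 (0.83 ± 0.19). Oxidative phosphorylation genes were higher in 1 of 15, Cyc1 (0.58 ± 0.13), or 10 of 15 adjusted over the list alone. Their mean scores were 0.27 in KO sham and -0.05 in WT sham, against -0.10 in KO IRI and -0.12 in WT IRI, so the fall after IRI in KO starts from a higher level. Glucocorticoid response genes were lower in 2 of 11, Zbtb16 (-3.71 ± 0.87) and Lcn2, with a median of -1.07. The camera adjusted p values of these lists were 0.000557 and 4.44e-06, and the adjusted p = 0.376 and 0.238 with an estimated correlation. All 8 erythrocyte genes lay above 0, but none passed and the list did not pass camera (adjusted p = 0.218, and adjusted p = 0.606 with an estimated correlation).

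In this comparison 2297 genes passed, 1329 higher and 968 lower, and the groups did not overlap for 42.7% of genes where chance gives 10%. The median over all genes was 0.125, and each gene was tested against 0, so the counts include that shift. With quantile normalization the split was 828 higher and 1093 lower, with a median of 0.064. All WT sham arrays were on 1 slide and all KO sham arrays on the other, so genotype and slide cannot be told apart. A fit to these 6 arrays alone gave 4042 genes. The count was 927, 1110 and 1441 without WT sham replicates 1, 2 and 3, 649, 1515 and 788 without KO sham replicates 1, 2 and 3, and 4405 without WT IRI replicate 1, and it was 9669 with array weights. The split turned to 454 higher and 473 lower without WT sham replicate 1, 649 and 792 without WT sham replicate 3, 303 and 346 without KO sham replicate 1, and 378 and 410 without KO sham replicate 3.

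**Figure D3:**
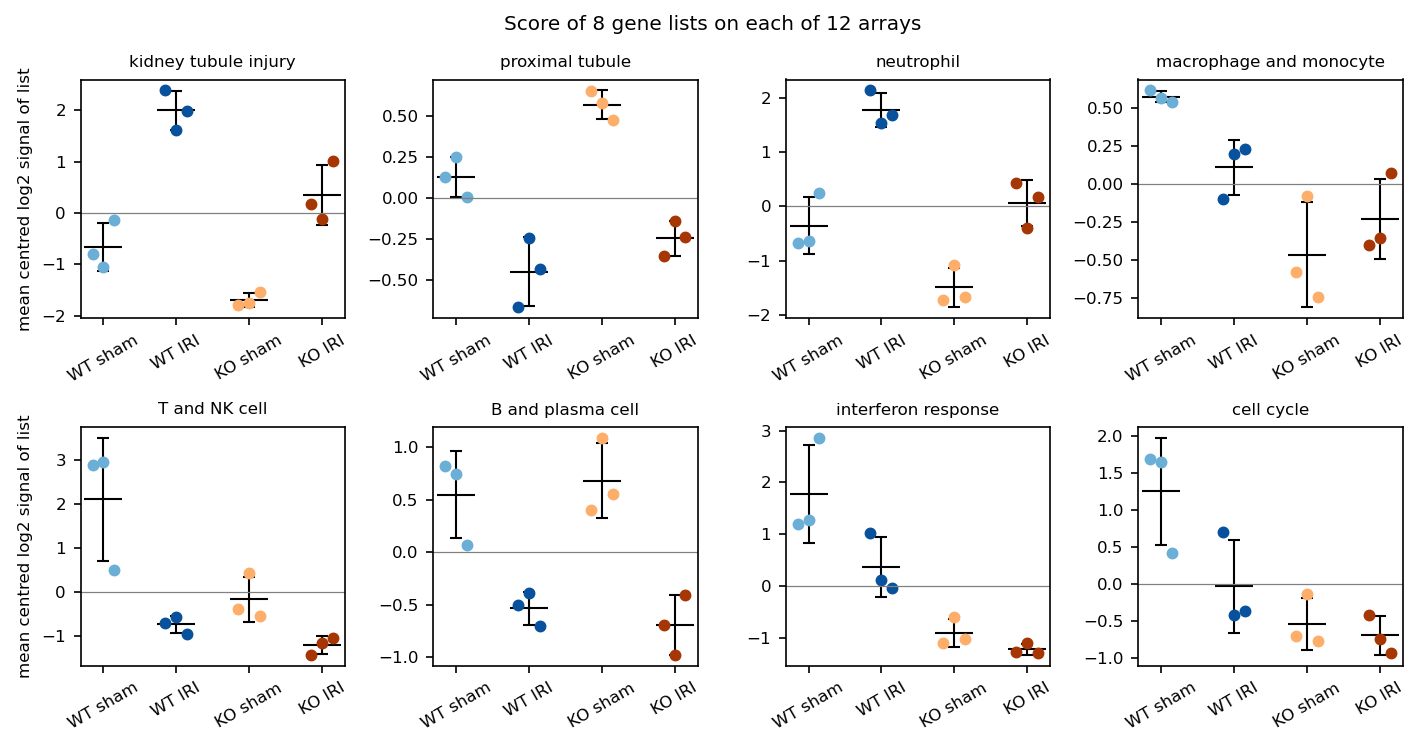
Score of 8 fixed gene lists (y axis, mean of centred log2 signals) in the 4 groups (x axis). Points are arrays and bars are means with SD (n = 3). WT sham replicates 1 and 2 lie at T and NK cell scores of 2.88 and 2.94, and the KO IRI neutrophil scores of -0.40 to 0.43 lie below the WT IRI scores of 1.54 to 2.13.

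In injured kidneys, the chemokine genes Cxcl3, Cxcl2 and Cxcl5 and 4 of 14 neutrophil genes were lower in KO than in WT animals. Cxcl3 and Cxcl2, which attract neutrophils, were not well above background on any KO IRI array and were at least 14.03-fold and 3.04-fold lower (adjusted p = 0.000490 for both). Acod1, the itaconate-producing enzyme of activated macrophages, was at least 14.6-fold lower and Slfn4 at least 8.69-fold lower, a call lost in 13 of 21 alternative fits. The smallest log2 changes of Cxcl3, Acod1 and Slfn4 over the alternative fits were -1.88, -1.68 and -1.48. Clec4e was lower by -3.43 ± 0.33 (adjusted p = 0.00267), with 2 of 3 KO IRI arrays well above background. Over the alternative fits the value of Clec4e ran from -3.56 to -1.50. With it Fcer1g (-0.81 ± 0.17) and the kinase Syk (-0.99 ± 0.19) made 3 of 11 lectin signalling genes that were lower (camera adjusted p = 0.000705, and adjusted p = 0.132 with an estimated correlation). Among 14 neutrophil genes 4 were lower, or 9 adjusted over the list alone, including Stfa2l1 (-3.63 ± 0.40), Retnlg (-3.49 ± 0.59) and the protease Mmp8 (-2.29 ± 0.48). That list had a camera adjusted p of 5.90e-07, and an adjusted p = 0.189 with an estimated correlation. None of 17 macrophage and monocyte genes and none of 11 dendritic cell and antigen presentation genes passed, with medians of -0.36 and -1.52 (camera adjusted p = 0.0388 and 0.00120, and adjusted p = 0.477 and 0.389 with an estimated correlation). None of 8 erythrocyte and none of 9 adipose genes passed over all genes, with medians of -1.45 and -1.30, and adjusted over the list alone 5 erythrocyte genes and 0 adipose genes were lower. Their camera adjusted p values were 0.0149 and 0.0220, and the adjusted p = 0.389 and 0.499 with an estimated correlation. Cytokine and chemokine genes had a median of -1.81, with Cxcl2, Cxcl5 and Lif past the threshold over all genes and 16 of 22 lower adjusted over the list alone (camera adjusted p = 1.76e-10, and adjusted p = 0.155 with an estimated correlation). The calls of Fcer1g, Mmp8 and Lif were lost in 12 of 22, 11 of 22 and 12 of 21 alternative fits.

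Interferon response genes were lower in 3 of 17, Irf7 (-2.97 ± 0.46), Mx1 (-2.61 ± 0.43) and Isg15 (-2.02 ± 0.41), with camera adjusted p = 2.53e-09 and adjusted p = 0.355 with an estimated correlation. In the tubule injury list Sprr2f (-5.55 ± 1.16), Plaur (-1.92 ± 0.29) and Atf3 (-2.22 ± 0.44) were lower, with a list median of -1.24 (camera adjusted p = 1.76e-10, and adjusted p = 0.189 with an estimated correlation). The calls of Sprr2f and Atf3 were lost in 11 of 21 and 11 of 22 alternative fits. The glycolytic enzyme gene Hk2 was lower (-2.62 ± 0.36), and so was the transcription factor gene Fosl1 (-4.16 ± 0.73). Havcr1 (-3.34 ± 1.15, adjusted p = 0.147) and Lcn2 (-1.30 ± 0.41, adjusted p = 0.121) did not pass. Of the 15 lists past camera the endothelium list alone moved up, with a median of 0.45 and none of its 13 genes past the threshold over all genes (camera adjusted p = 0.00187, and adjusted p = 0.355 with an estimated correlation). The largest rises were in genes near background, such as Nmur1 (at least 2.52-fold) and Gipr (at least 1.56-fold), whose call was lost in 11 of 21 alternative fits. In all, 501 genes passed, 236 higher and 265 lower, and the groups did not overlap for 21.8% of genes where chance gives 10%. With normexp there were 329, 66 higher and 263 lower, and Cxcl2 no longer passed (-0.64). The count was 279 with the replicate number as a block, 335 without a filter and 2034 with array weights. The split was 155 higher and 415 lower without KO IRI replicate 1, and turned to 343 higher and 293 lower without WT IRI replicate 1 and 519 and 452 without WT IRI replicate 2. Genotype and slide cannot be told apart here either, and a fit to these 6 arrays alone gave 35 genes. The count was 317 and 328 without WT sham replicates 1 and 2, 971 and 245 without WT IRI replicates 2 and 3, 297 and 276 without KO sham replicates 1 and 3, and 146 without KO IRI replicate 2.

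The interaction asked in which genes the IRI response itself differed between genotypes. The chemokine genes Cxcl3 and Cxcl2 had a smaller response in KO than in WT (adjusted p = 0.00593 for both). They were well above background in WT IRI alone, so no size is given. Cyp24a1, which degrades active vitamin D, had an interaction of -4.10 ± 0.52. The neuropeptide gene Grp passed as well (adjusted p = 0.0428), but it was well above background on no sham array, so no size is given, and its call was lost in 12 of 21 alternative fits. The interaction of Clec4e did not pass (adjusted p = 0.587), and no size is given because it was well above background on no KO sham array. Neither did that of Lcn2 (0.37 ± 0.58) or Havcr1 (-0.19 ± 1.63) pass. Of 25947 genes 18 passed, 5 higher and 13 lower, against 2536 at an unadjusted p under 0.05. Camera passed 17 lists, among them T and NK cell (median 2.13), cell cycle (1.35) and interferon response (0.99) genes in the direction of a smaller fall in KO. None passed with an estimated correlation (lowest adjusted p = 0.338 with an estimated correlation) or by fry. The count was 4, 6 and 59 without WT sham replicates 1, 2 and 3, 148 without WT IRI replicate 1, 5 and 4 without KO sham replicates 1 and 3, and 7, 5 and 30 without KO IRI replicates 1, 2 and 3. It was 37 with normexp, 10 with the stricter filter, 9 with the mean over probes, 5 with the replicate number as a block and 1353 with array weights. The split of 5 higher and 13 lower did not hold in all fits, with 39 higher and 20 lower without WT sham replicate 3, 85 and 63 without WT IRI replicate 1, 8 and 7 without KO sham replicate 2, and 697 and 656 with array weights.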

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

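The tests below were chosen after the results were seen, except the counts over other splits of the arrays, which were planned. Groups of 3 arrays are too small for a test of single outlying arrays, and the genes and lists below are given because they passed the threshold of the interaction. The 3 patterns weighed after them come from KO against WT.

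Of the genes past the threshold of the interaction, the naming rule takes 10. Cxcl3 (-6.25), Crtac1 (-4.72), Cyp24a1 (-4.10), Cxcl2 (-4.03), Grp (-3.79) and DXBay18 (-3.34) responded less or fell in KO relative to WT, and Gpr33 (3.17), Plaat3 (1.16), Hyls1 (1.15) and Ihh (1.05) went the other way. Cxcl3, Crtac1 and Cxcl2 were well above background in WT IRI alone and Gpr33 in WT sham alone, Grp was well above background on no sham array, and another probe of Ihh had the opposite sign. The values of Cxcl3, Crtac1, Cxcl2, Gpr33 and Grp therefore depend on the background level and are not measured sizes, and that of Grp ran from -4.25 to -2.18 over the alternative fits. The calls of Grp, Plaat3, Hyls1 and Ihh were lost in 12 of 21, 11 of 22, 12 of 22 and 15 of 22 alternative fits. Of 100 drawn splits of the genotype labels within sham and within IRI, from 200 distinct ones, 5 gave at least the 18 genes of the real split. These include the real split and the highest other split. Exchanging single arrays also moves the genotype difference into the spread, and 71 splits gave 0 genes. The share is therefore not a clean test, and chance cannot be excluded for this count. The highest other split gave 3895 genes. It exchanges the genotype labels in 1 condition only, so it measures the genotype or slide difference itself, and the highest of the remaining splits gave 178.

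Lists that passed camera in the interaction, none of them with an estimated correlation, had these medians. Upward were T and NK cell (2.13), cell cycle (1.35), dendritic cell and antigen presentation (1.13), interferon response (0.99), macrophage and monocyte (0.92), complement and coagulation (0.77), glucocorticoid response (0.74), heat shock and unfolded protein response (0.35), collecting duct (0.26), podocyte (0.20), regulated cell death (0.17) and the chromosome 9 neighbours of Jaml (0.15), a list that holds the T cell genes Cd3d, Cd3e and Cd3g. Downward were adipose (-3.38), erythrocyte (-2.10), liver (-0.53), oxidative phosphorylation (-0.29) and proximal tubule (-0.27).

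For the 4 comparisons of 3 arrays against 3, only 10 splits exist, too few for a share under 0.05. In fits to the 6 arrays of each comparison, the real split gave 417 genes for WT IRI against WT sham, where 1 of 10 splits, the real one, gave as many and the highest other split gave 1. It gave 2442 for KO IRI against KO sham, 4042 for KO sham against WT sham and 35 for KO IRI against WT IRI, with 0 in the highest other split of each.

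T and NK cell, dendritic cell, interferon and cell cycle genes were higher in WT sham than in KO sham kidneys. Their mean score differed by -2.33 (KO minus WT, 95% interval -3.04 to -1.61) in sham and by -0.98 (-1.70 to -0.27) in IRI. Lymph node tissue taken along with the WT sham kidneys stays open. The T and NK cell score differed by 2.41 (1.42 to 3.40) more than the B and plasma cell score, but within WT sham the scores moved together. Replicates 1 and 2 had 2.88 and 2.94 for T and NK cells and 0.82 and 0.75 for B and plasma cells. Replicate 3 had 0.50 and 0.07, yet the highest interferon score, 2.861 against 1.198 and 1.265. Its dendritic cell score of 1.95 was close to the 1.971 and 2.005 of replicates 1 and 2. The interferon and dendritic cell scores thus did not follow the T and B cell scores, though this rests on 1 array. The KO sham B and plasma cell scores were 0.40 to 1.09, so that baseline was not low. A slide or scan difference stays open. The interaction of the mean score of the 4 lists was 1.34 (0.33 to 2.36), but these lists were picked among those past the threshold of the interaction. None of them taken singly had an interval that excluded 0 (lower ends -0.42 to -0.17). Genotype itself and the state of these WT animals stay open as well, because the difference of -0.98 in IRI lies between slides too.

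Clec4e, Cxcl2, Cxcl3 and neutrophil genes were lower in KO IRI than in WT IRI kidneys. Their mean score had an interaction of -1.13 (95% interval -2.02 to -0.23), but Cxcl2 and Cxcl3 in it were picked for passing the interaction, and only 11 of the 17 genes were well above background on all 6 sham arrays. The neutrophil list alone did not pass in the interaction (median -0.65, camera adjusted p = 0.440, and adjusted p = 0.850 with an estimated correlation). A slide or scan difference therefore stays open. Milder injury of the KO kidneys stays open as well. The tubule injury score was lower by -1.64 (-2.44 to -0.84) in KO IRI, while the proximal tubule score differed by 0.20 (-0.06 to 0.46), which does not settle it. In sham the tubule injury score already differed by -1.035 and the proximal tubule score by 0.441 (KO minus WT). Much of the difference in injury score was therefore present without IRI. Fewer neutrophils may account for part, and 2 of the 14 neutrophil genes fell by at least as much as Clec4e, so this cannot be told apart from a lower level per cell.

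Jaml was lower in KO, but signal remained. Between the lowest WT and the highest KO sham array lay a gap of 2.15. It would speak against a wrong genotype label in sham only if the probe reads the deletion, which is not known. The gap among IRI arrays was 0.089, too small to exclude a wrong label there in any case. Fewer leukocytes in KO kidneys stay open, since the mean of a list is diluted by members that do not fall. Averaged over sham and IRI, the KO minus WT value of Jaml differed by -1.103 (95% interval -1.963 to -0.243) from that of the mean score of 5 leukocyte lists, which itself was -1.07. That mean holds B and plasma cells, which did not fall in sham (0.14). From the macrophage and monocyte score Jaml differed by -1.49 (-2.63 to -0.35), or -1.23 (-2.85 to 0.39) in IRI alone, and from the B and plasma cell score by -2.17 (-3.18 to -1.15), or -1.41 (-2.84 to 0.02) in IRI alone. It differed from the dendritic cell score by -0.30 (-0.79 to 0.19) and from the T and NK cell score by -0.81 (-2.14 to 0.53). From the neutrophil score it differed by -0.75 (-1.62 to 0.11), or -1.65 (-2.87 to -0.43) in sham and 0.14 (-1.08 to 1.37) in IRI.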

How the results depend on the processing

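All alternatives were planned. Of the 236 calls on named genes, 227 held with quantile normalization or the authors' values, 210 with normexp, 193 without a filter, 220 with the mean over probes and 192 with the replicate block. Of the 226 outside the interaction, 131 held in fits to the 6 arrays of a comparison. Leaving out 1 array kept 142 (without WT sham replicate 1 or KO sham replicate 1) to 220 (without WT IRI replicate 1). No gene that passed in the fit as planned changed direction except Tnf, KO sham against WT sham, at -1.02 with the mean over probes. The interactions of Havcr1 and Lcn2, which never passed, also changed sign. Without 1 array that of Havcr1 ranged from -1.66 (without KO IRI replicate 3) to 0.93 and was 0.05, 0.29, 0.23, 0.04, 0.93 and 0.15 (without WT sham replicates 1 and 2, WT IRI replicates 2 and 3, and KO IRI replicates 1 and 2), and that of Lcn2 ranged from -0.12 (without WT IRI replicate 2) to 0.892 (without WT IRI replicate 1). Array weights raised the counts to 8922 (WT IRI against WT sham), 5756 (KO IRI against KO sham), 9669 (KO sham against WT sham), 2034 (KO IRI against WT IRI) and 1353 (genotype by IRI interaction). With only the groups of the contrast, they were 417, 2442, 4042 and 35 in the first 4 comparisons. In the fit as planned they were 3109, 1598, 2297 and 501, so the comparisons with WT IRI fell and the others rose. The WT IRI arrays deviated from their group mean by 0.341 to 0.579, against 0.205 to 0.362 on the other arrays. The shared spread can therefore be too small for comparisons with WT IRI and too large for the others. KO IRI against WT IRI gave 329 with normexp, and the interaction 37 with normexp, 10 with the filter on all 12 arrays and 9 with the mean over probes. The cause was not tested, though normexp with an offset compresses dim genes. The correlation of the IRI response between genotypes was 0.648 with normexp, 0.529 without a filter, 0.630 with the stricter filter and 0.526 with array weights. Over the fits without 1 array the counts ranged from 846 to 4675, 454 to 3250, 649 to 4405, 146 to 971 and 4 to 148 in the order above, the correlation from 0.551 to 0.605, Jaml in KO against WT from -3.04 to -2.57 in sham and -1.99 to -0.81 in IRI. Lists past the threshold ranged from 17 to 21, 13 to 17, 15 to 16, 12 to 15 and 12 to 19. With an estimated correlation they were 0, 0, 2, 0 and 0, and by fry 20, 12, 17, 8 and 0. Slide as a block changed no count of the IRI comparisons or the interaction, where its term adds nothing to the group terms.

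The replicate numbers were not treated as pairs, and correlations of same-numbered deviations ran from -0.267 to 0.151. In KO IRI against WT IRI they were 0.14, 0.116 and 0.075, so pairing is not excluded there. With the replicate number as a block the counts were 2484, 1153, 1782, 279 and 5, and 2, 0, 3 and 5 of 6 arrays correlated best with their own number in the first 4 comparisons. Probes near background limit Cxcl2, Cxcl3 and Clec4e, whose signal in some groups was not well above background.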

Other observations

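The genes and lists in this part are given as values.

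Some genes for partners and relatives of Jaml were measured too. Cxadr, which encodes its epithelial ligand CAR, had log2 fold changes of 0.07 ± 0.13 after IRI in WT and 0.06 ± 0.13 in KO (SE, n = 3 per group). Jam2 rose in both, by 1.11 ± 0.17 in WT (adjusted p = 0.00580) and 0.91 ± 0.17 in KO (adjusted p = 0.0155), and F11r did not pass in either (0.27 ± 0.19 and 0.09 ± 0.19).

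Adipose scores varied between arrays of a group, from 0.04 to 3.14 in WT IRI and from -0.93 to 1.54 in KO sham, while erythrocyte scores were 0.69 to 0.82 on all 3 WT IRI arrays and -0.91 to -0.48 in WT sham. None of the 15 circadian clock genes passed in KO IRI against WT IRI, and in KO sham against WT sham 1 was lower. None of 6 mouse substrain genes passed in KO IRI against WT IRI, and 1 was lower in KO sham than in WT sham. The 19 genes neighbouring Jaml on chromosome 9, 3 of which are T cell genes, had a median of 0.09 in KO IRI against WT IRI, and none passed. In KO sham against WT sham their median was -0.01 and 3 were lower, Cd3d, Cd3g and Il10ra.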
